A study of Homo sapiens with 2 samples.

How the data were processed

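Chromatin from cross-linked MDA-MB-231 cells was enriched with an antibody against mTOR, and a library was sequenced from it and another from input chromatin, per the labels' protocols. The trimmer Trimmomatic 0.36, the aligner BWA 0.7.12, Picard 2.0.1, the peak caller MACS2 2.1.1.20160309, HOMER 4.11.1 and the build hg38 are named, without settings, per the submitters' processing notes. Therefore the peak threshold, the treatment of duplicate reads and of reads that align to several places are not given in the sources used here. Each of these could change the peaks over repeats and gene families. The processed data are 1 table of annotated peaks for the mTOR ChIP library. No file of the input library was analysed here.

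Each line of the table gives a peak's position, a score deposited by the authors as a whole number without a stated scale, an annotation class, a repeat or other detailed annotation of the peak centre, the distance to the nearest start site and the nearest gene. The distance and the positions are used as deposited. Peaks of the 1 library were called once, so no peak set can be compared between replicates, and the depth and its effect on the number of peaks are unknown. All 21440 peaks lay on chromosomes 1 to 22 and X. Gene names and spans came from a table of human genes on GRCh38 p14, the same assembly as hg38 at a later patch. It held the gene identifiers of 99.7% of the peaks. It has no strand, exons or sequence.

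Shares of peaks have exact Clopper-Pearson 95% intervals. Random placement moved each peak to a random position on its chromosome between the first and last annotated gene, 100 times. A protein-coding gene had a promoter peak when a peak assigned to it by the deposited annotation overlapped 1 kb either side of the start site, as computed from the deposited distance and the peak width. There were 19974 protein-coding genes on these chromosomes, of which 3097 had such a peak. The 28 gene lists were 24 lists of symbols and 4 name patterns, fixed before the data were examined, as were the tests and most of the alternative settings. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 28 lists and a threshold of 0.05. Odds ratios had 0.5 added to each cell, with Wald standard errors. Genes named as nearest gene were compared with 10000 random lists of the same size, matched on gene length in 10 classes, whose smallest two-sided p is 0.00020.

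List symbols were matched to current symbols, and to a synonym only where the symbol names no current gene. This matching was corrected after first values had been seen, because a T-cell receptor segment of the immune list had been taken for an unrelated gene. The correction left the immune list with 33 genes and moved no list across the threshold. The genes named are those of the 15 top-scoring promoter peaks and the 10 top peaks, up to 3 top members of each list, 10 genes named in advance and any ribosomal protein gene with a promoter peak. Some of the genes this rule gives are not reported here. Alternatives were the 10720 and the 2144 peaks with the highest scores, start-site windows of 100 bp and 5 kb, the deposited promoter class, a peak with most of its length in the window, no length matching and a limit of 10 kb. Added after the data were seen were windows at either end of a gene span, peaks with a repeat label left out, satellite peaks left out and chromosome 19 left out. The list test was tested on simulated promoter peaks for the 19974 genes: with 3 lists at an odds ratio of 3 in 100 simulations, 82.3% of these lists were called, the mean log2 odds ratio was 1.61 for a simulated 1.58, and 0.52% of unchanged lists were called.

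Motifs in the peaks, lists matched on promoter GC content, a background of GC-rich promoters and classes recomputed from gene models need a genome sequence or exon models, which were not used here. The promoter definition by deposited distance is the form set in advance for that case. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.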

Results

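Chromatin bound by mTOR, the kinase that couples nutrient and growth factor supply to cell growth, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in MDA-MB-231, an established human triple-negative breast cancer cell line grown in serum. The series concerns ribosomal gene expression and senescence under a nuclear complex of PML, mTOR and RONIN, the zinc finger DNA-binding protein encoded by THAP11. There was 1 mTOR ChIP library and 1 input library, the chromatin without enrichment, and the data are the 21440 peaks called for the ChIP library with their annotation on the hg38 build. Neither library has a replicate, so the intervals given here cover counting error only, and the peaks and genes counted are not replicates. The depth of the libraries is unknown, since the peak list carries no read counts. Peaks were 248 to 4531 bp wide with a median of 400 bp and covered 10.7 Mb. The deposited peak score ran from 13 to 5636 with a median of 61, is the authors' own value on a scale not given in the sources used here, and serves below only to rank and select peaks.

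The first question was where in the genome mTOR peaks lay. Intergenic sequence held 43.6% of the 21440 peaks (exact Clopper-Pearson 95% interval 42.9 to 44.2%) and introns held 37.8% (37.2 to 38.5%). Promoters, in the deposited promoter-TSS class, held 2797 peaks or 13.0% (12.6 to 13.5%), and exons held 521 peaks or 2.43% (2.23 to 2.65%). Median scores were 61 in intergenic sequence, 59 at promoters and 57 in introns. Exon peaks were the widest of the 8 classes, with a median of 721 bp against 441 bp at promoters, and their upper score quartile was 160 against 106. Chromosome 19, which is rich in genes and in zinc finger gene clusters, carried 31.4 peaks per Mb, while the median of the 22 autosomes was 6.77 and the lowest, chromosome 13, had 2.54. Per 100 protein-coding genes chromosome 19 was not the highest, with 126.9 peaks against 164.8 on chromosome 18. The X chromosome carried 143 peaks, 0.917 per Mb.

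Repeats lay under the centres of 64.4% of peaks (63.8 to 65.1%). L1 elements, the retrotransposons that make up the most abundant LINE family, held 7337 peaks or 34.2% (33.6 to 34.9%), led by L1PA5 with 705 and L1PA7 with 628. Of these L1 peaks 7.02% belonged to the 2144 top-scoring peaks, whose lowest score was 200, a cut that fell within peaks tied at 200. Endogenous retroviral ERV1 sequences had 1608 peaks, a median score of 92.5 and 25.1% of their peaks in that top set. The ERVL-MaLR family held 1810 peaks, of which 1242 lay in THE1 and MST elements. Centres without a repeat label numbered 7627, with a median score of 54. How much of the genome each family occupies was not used here, so these shares are not enrichments.

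**Figure D1:**
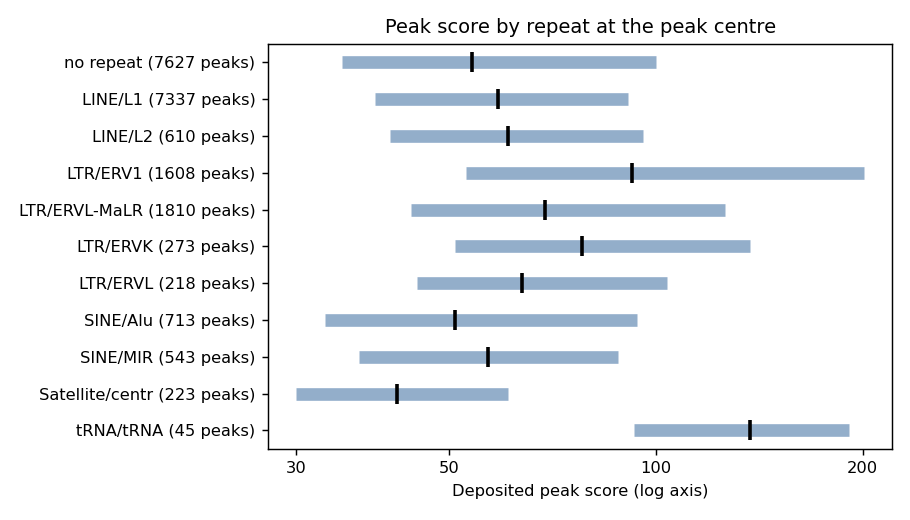
Deposited peak score (log axis) by the repeat family labelled at the peak centre, with the number of peaks per family. The group without a repeat holds peaks with no such label. Boxes span the quartiles and ticks mark the medians over peaks of the 1 library; the ERV1 median was 92.5 and the L1 median 59.

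The second question was how closely the peaks followed transcription start sites. Of all peaks, 3606 (16.8%, 16.3 to 17.3%) had their centre within 1 kb of the nearest start site, and 88.2% of these belonged to protein-coding genes. Their centres gathered just upstream of the start, at a median of -41 bp, with 56.5% (54.9 to 58.2%) on the upstream side. The most distant part of the list was also large: 30.1% of peaks lay more than 50 kb from any start, and the median distance over all peaks was 21627.5 bp. Random placement of the same peaks along their chromosomes, repeated 100 times, put 3.02% (2.75 to 3.29%) of centres within 1 kb of either end of a protein-coding gene span, against 15.2% observed, a ratio of 5.03. Inside gene spans the observed share was 45.8% and the random share 44.0% (43.1 to 44.7%), a ratio of 1.04. Gaps in the genome sequence were not left out of this placement, which ran between the first and last annotated gene of each chromosome.

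**Figure D2:**
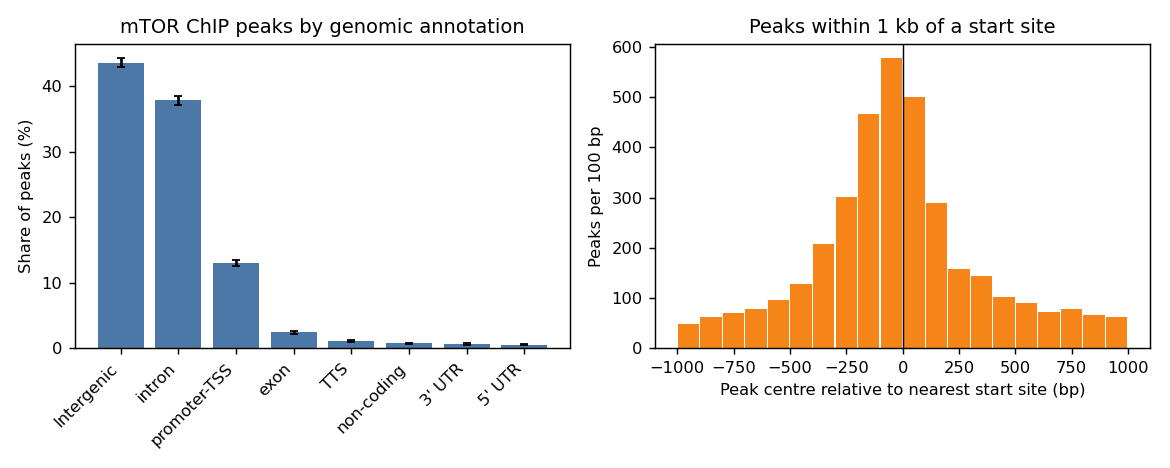
Left, share of the 21440 mTOR peaks in each annotation class in percent, with exact 95% binomial intervals as bars; intergenic sequence and introns come first with 43.6% and 37.8%. Right, number of peak centres per 100 bp against their distance in bp from the nearest start site, for the 3606 centres within 1 kb.

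The strongest promoter peak was at NPAS4, an activity-dependent neuronal transcription factor gene (chromosome 11, 66418396 to 66422926), with a score of 4542 and the greatest width in the list. KMT5B, which encodes a histone H4 lysine methyltransferase, followed with 2407 (chromosome 11, 68213073 to 68214345, 61 bp upstream of the start). AP2S1, a subunit of the clathrin adaptor AP-2, had 2038 (chromosome 19, 46850711 to 46851474). POR, the electron donor of microsomal cytochrome P450 enzymes, had 1692, and PDE4A, a cAMP phosphodiesterase, had 1586. The other 10 of the 15 top promoters were those of ADGRL1, XKR7, LIN28A, HYAL2, ITPRIP, MNT, QRICH1, POC1B, ATL3 and HSPD1, with scores from 1414 down to 1092. Centres of the ADGRL1, LIN28A and HYAL2 peaks lay at -1108, -1683 and 1074 bp, so these peaks reached the 1 kb window only by their width. Those of ADGRL1 and LIN28A were deposited as intergenic. MNT encodes a repressor that pairs with MAX, and HSPD1 the mitochondrial chaperonin HSP60. Among all peaks the top score, 5636, belonged to an intergenic site beside the centromere of chromosome 1 (125180008 to 125180528), whose nearest annotated start, EMBP1, was 3661156 bp away. A second peak there, at 125182341 to 125182723, ranked 3 with 3070. The remaining top 10 lay nearest to CHST3, HIF1A-AS3, KBTBD6-DT, WDR45B, SEC23A-AS1 and LSP1P5 by the deposited annotation, beside those at NPAS4 and KMT5B. The LSP1P5 peak (chromosome 1, 143214500 to 143214872) was deposited as 207906 bp from a start of that gene. In the gene annotation used here, however, LSP1P5 begins at 144716079. A control antibody library was not analysed here, so loci that many antibodies enrich stay open for the top peaks.

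Ribosomal protein genes were the group named by the series, and 30 of the 79 cytosolic ones (38.0%, 27.3 to 49.6%) had a peak within 1 kb of their start site, against 15.4% of the other protein-coding genes. RPL26, RPS7 and RPS14 had the highest scores, 237, 182 and 176, and RPL6, RPL32, RPS26, RPL29, RPL4 and RPL14 had 100 or more. The RPL26 peak covered 8382958 to 8383692 on chromosome 17, centred 132 bp upstream of the start. RPL5, whose product binds MDM2 when ribosome assembly is disturbed, had 74, and RPS19, mutated in Diamond-Blackfan anaemia, had 77. The log2 odds ratio was 1.76 (SE 0.33), with p = 9.8e-07 by a two-sided Fisher's exact test and 9.2e-06 after Benjamini-Hochberg adjustment over 28 gene lists. Among the 2144 top-scoring peaks RPL26 alone had one, where the share of the other genes would give 1.24 genes, too few to show a direction. Against 334 genes of 6 other housekeeping lists, a comparison chosen after the values were seen, the log2 odds ratio was 0.48 (-0.25 to 1.22).

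Other genes of the translation machinery also carried promoter peaks more often than the remaining genes. Of the 78 mitochondrial ribosomal protein genes 28 had one (35.9%), with MRPL34 at 137, MRPS17 at 125 and MRPS23 at 118. Translation factors followed with 17 of 49 (34.7%), among them the helicase gene EIF4A2 at 260, the release factor gene GSPT1 at 191 and EIF4E, the cap-binding protein restrained by the mTOR substrates 4E-BP, at 159. RNA polymerase I and III genes had 12 of 37 (32.4%), with POLR3E at 358, GTF3C5 at 237 and POLR3K at 191. Ribosome biogenesis genes had 21 of 77 (27.3%), with WDR36 at 507, NOC3L at 229 and WDR43 at 188. Their log2 odds ratios were 1.63, 1.56, 1.42 and 1.06 in that order, with adjusted p-values from Fisher's exact test of 4.6e-05, 0.0035, 0.023 and 0.018. With windows of 5 kb the adjusted p-values of the last 3 lists were 0.056, 0.071 and 0.080 (Fisher's exact test, log2 odds ratios 1.08, 1.12 and 0.76). With the higher-scoring 10720 peaks those of translation factors and ribosome biogenesis were both 0.064 (Fisher's exact test, 1.35 and 1.11). Aminoacyl-tRNA synthetase genes, which charge tRNAs, had 8 of 40 (adjusted p = 0.47, Fisher's exact test), with EARS2 at 414.

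Genes of RONIN, HCF-1 and their chromatin partners had a promoter peak in 9 of 21 (42.9%, 21.8 to 66.0%), led by the histone H3 lysine 4 methyltransferase genes KMT2A at 496 and SETD1A at 200 and by ZNF76 at 164. THAP11 itself had a peak across its start site (chromosome 16, 67841880 to 67842735) with a score of 80. The list's log2 odds ratio was 2.05 (SE 0.62), with p = 0.0025 and an adjusted p of 0.0079 by Fisher's exact test. With start-site windows of 5 kb the adjusted p was 0.062. HCFC1 and PML had no peak in or within 1 kb of the gene, and CDKN2A had none either. Whether these loci are intact in this cell line was not examined here, so a missing peak does not show missing binding. HCFC1 lies on the X chromosome, where peaks were few for any gene. It carried 16.9 peaks per 100 protein-coding genes, against 76.3 on chromosome 22, the lowest autosome. Of 29 PML body genes 6 had a promoter peak, among them SUMO2 at 322 and PIAS1 at 96 (adjusted p = 0.49, Fisher's exact test).

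Genes of the mTOR pathway had a promoter peak in 16 of 56 (28.6%), a log2 odds ratio of 1.15 with adjusted p = 0.028 by Fisher's exact test. FLCN, a regulator of Rag GTPases, had 440, TSC1, a brake on mTORC1, had 248, and SEH1L, part of the GATOR2 complex, had 225. RPTOR, the substrate-binding subunit of mTORC1, had a peak of score 50 at its start (chromosome 17, 80544642 to 80545051). RICTOR, its counterpart in mTORC2, had 3 peaks assigned and none at the promoter, and MTOR had a single intronic peak of score 87 in intron 29 over an L1PA5 element, assigned to ANGPTL7. This call ended in 6 of 9 alternative settings, with adjusted p-values over the 9 from 0.011 to 0.46 by Fisher's exact test. The log2 odds ratio in those 6 ran from 0.90 to 2.05, the latter from 3 genes among the 2144 top-scoring peaks.

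Senescence genes were not told apart from the rest. Senescence regulators had 8 of 41 promoters with a peak (log2 odds ratio 0.47, adjusted p = 0.55, Fisher's exact test), and the log2 odds ratio changed sign, with -0.96 for windows of 100 bp and 1.19 for the higher-scoring 10720 peaks. They included HMGB1 at 510, GADD45B at 283 and CDKN1A at 182. The CDKN1A peak, near the gene for the cell cycle inhibitor p21, lay in intron 1 with its centre 1477 bp from the assigned start (chromosome 6, 36679596 to 36680786). Secretory factors of senescent cells had 7 of 51 (log2 odds ratio -0.12, adjusted p = 0.85, Fisher's exact test), and -1.44 with the higher-scoring 10720 peaks, with IGFBP7 at 82, CSF1 at 60 and IGFBP3 at 44. ZNF143, which binds many of the same promoters as RONIN, had a peak of score 156 at an end of the gene that was assigned to LOC644656. Each peak counted for 1 gene only, so divergent promoters are undercounted.

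Several other lists, of varied function, were also higher. Splicing factor genes had 24 of 60 (40.0%, log2 odds ratio 1.88, adjusted p = 2.6e-05, Fisher's exact test), with SF3A2 at 280, SNRPB at 251 and SNRPB2 at 196. Histone genes had 24 of 70 (log2 odds ratio 1.53), with H4C8 at 260, and proteasome genes had 11 of 32 (1.55), with PSMC3 at 404 and PSMB3 at 201. Cell cycle and replication genes had 17 of 63 (1.04), with CDC45 at 331, GINS3 at 285 and RFC1 at 248. Among ZNF genes, which encode zinc finger proteins, 122 of 509 had one (0.81), with ZNF335 at 978, ZNF562 at 823 and ZNF473 at 545. The adjusted p-values of the last 4 groups, from Fisher's exact test, were 0.00035, 0.024, 0.040 and 6.1e-06. The histone call ended in 3 of 9 alternative settings. Among these, the deposited promoter class gave 13 of 70 (log2 odds ratio 0.79) and the higher-scoring 10720 peaks 9 of 70 (0.94). The adjusted p was 0.16 in either (Fisher's exact test). The H4C8 peak was centred at -977 bp from the assigned start. Neighbouring histone genes were counted as separate genes, and whether their peaks also overlapped tRNA genes was not tested. In all, 12 of the 28 lists were higher, 3 were lower and 13 were not called. The 2144 top-scoring peaks left a median of 0.978 expected genes per called list, too few for most lists to be tested. In every other alternative setting 5 of the 15 calls held, those of cytosolic and mitochondrial ribosomal proteins, splicing factors, ZNF genes and olfactory receptors.

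Lists of genes expressed mainly in other tissues had few peaks. Olfactory receptor genes had 2 of 390 promoters with a peak, OR1F1 and OR2D3, keratin-associated protein genes had 1 of 94, KRTAP4-6, and liver markers had 0 of 35, for which the exact 95% interval reaches 10.0% and a limit of 3 counts 8.57%. Adjusted p-values of these 3 lower lists were 2.3e-24, 2.6e-05 and 0.012 by Fisher's exact test. The liver call ended with the higher-scoring 10720 peaks and windows of 5 kb (adjusted p = 0.16 and 0.066), and the keratin-associated call with windows of 5 kb (0.056, Fisher's exact test, log2 odds ratio -1.04). Neuron, muscle and immune cell markers had 1 of 35, 2 of 36 and 1 of 33 and were not called (adjusted p = 0.060, 0.15 and 0.079, Fisher's exact test). Neuron markers were called lower with the deposited promoter class and with windows of 100 bp (adjusted p = 0.0358 and 0.0497), and immune markers with either end of the gene span (0.027, Fisher's exact test). Basal and mesenchymal breast markers, the class of this cell line, had 7 of 29, with the receptor tyrosine kinase gene AXL at 308, and luminal markers had 5 of 31, with MLPH at 53 (adjusted p = 0.27 and 0.84, Fisher's exact test). The AXL peak was deposited in intron 4, with its centre at -1214 bp from the assigned start. Autophagy and lysosome genes had 15 of 60, with ATG13 at 314 and TFEB, the lysosomal master regulator, at 259. Cholesterol synthesis had 7 of 26, with CYP51A1 at 159, glycolysis 6 of 24, with PFKM at 168, and oxidative phosphorylation 14 of 75, with NDUFS7 at 234. Their adjusted p-values were 0.079, 0.15, 0.32 and 0.49 by Fisher's exact test. Autophagy and lysosome genes were called higher with the higher-scoring 10720 peaks and with the deposited promoter class (adjusted p = 0.044 and 0.034, Fisher's exact test).

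**Figure D3:**
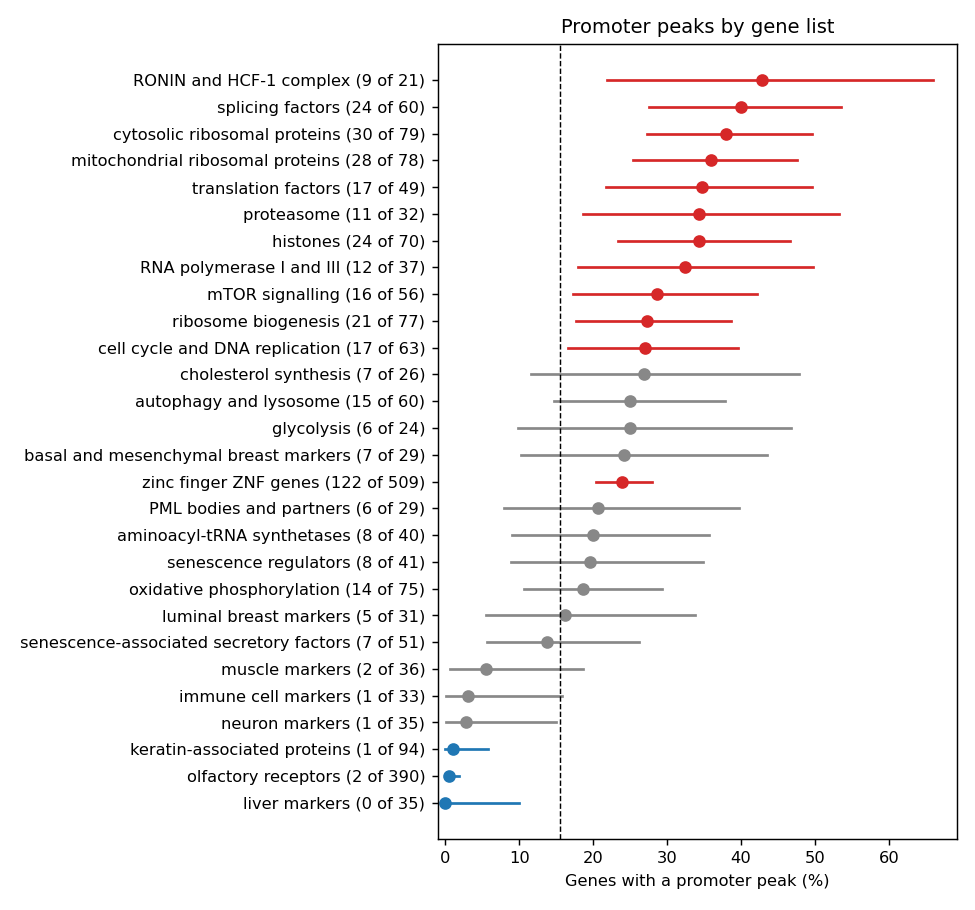
Share of genes with a promoter peak, in percent, for the 28 gene lists, with exact 95% binomial intervals; the dashed line marks all protein-coding genes at 15.5%. Red lists were higher and blue lists lower than the other genes after adjustment, and grey lists were not called.

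Assignment of every peak to its nearest gene, promoter peaks included, asked whether the same groups stood apart when distance was not limited. ZNF genes did, with 328 of 509 (64.4%) named as nearest gene of a peak against a mean of 41.6% in 10000 random lists matched on gene length. Mitochondrial and cytosolic ribosomal protein genes had 42 of 78 (53.8%, random 35.0%) and 39 of 79 (49.4%, random 30.5%). Of these genes 28 and 30 already had a promoter peak, as had 122 of the ZNF genes. Both tests therefore share peaks, and this one does not show that a group stood apart away from promoters. Olfactory receptor genes lay below, with 63 of 390 (16.2%, random 28.2%). Two-sided permutation p-values adjusted over the 28 lists were 0.0028, 0.0056, 0.0070 and 0.0028 in that order, and the other 24 lists were not called. The higher-scoring 10720 peaks kept the ZNF and olfactory receptor calls but gave adjusted p-values of 0.97 and 0.16 for the mitochondrial and cytosolic ribosomal lists (permutation test). Without matching on gene length these were 0.21 and 0.52.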

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

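Windows at either end of the gene span, repeat, satellite and chromosome 19 peaks left out and the settings for tRNA genes and last exons were chosen after the data were seen. Of 9 alternatives, the call for cytosolic ribosomal proteins ended only among the 2144 top-scoring peaks; the others gave log2 odds ratios from 1.28 to 2.26. That set had 1 gene of the list with 1.24 expected, so its log2 odds ratio of 0.26 shows no direction. Without the 0.5 added to each cell it was -0.31. That smaller set had 0 lists higher and 0 lower, with 2 lists at an unadjusted p under 0.05 by Fisher's exact test. There the RONIN list had 2.20 from 1 of 21 genes with 0.328 expected (1.65 without the 0.5 added to each cell; adjusted p = 0.72, Fisher's exact test) and mitochondrial ribosomal proteins -1.33, from 0 of 78 genes with 1.23 expected (adjusted p = 1, Fisher's exact test). Shares in that set were 13.8% promoter-TSS, 46.5% intergenic, 31.8% introns, 16.0% within 1 kb of a start and 21.9% of tRNA genes. The higher-scoring 10720 peaks gave 45.6% intergenic, 36.3% introns, 15.5% within 1 kb, 7 higher lists and 2 lists called by nearest gene. Windows of 5 kb gave 6 higher lists, 1 lower list and 1.58 for the RONIN list (adjusted p = 0.062, Fisher's exact test). Within 100 bp lay 5.05% of centres and within 5 kb 26.3%, by construction. Leaving out chromosomes 1 and 6 gave 66.3% of tRNA genes. Except for the smaller sets and other windows, the cause was not tested. Among 24 further lists, only 13 had a call, and all 13 lost it among the top-scoring 2144 peaks. Of these 13, 7 lost it among the higher-scoring 10720, 7 with windows of 5 kb and 3 with the deposited promoter class. With either end of the gene span 2 lost it, and without chromosome 19 1 did. Among all 15 called lists, the log2 odds ratio without that addition was as large or larger in 4 of the 15 losses in the top-scoring set, smaller in 7 and undefined in 4; in the higher-scoring 10720 it was as large or larger in 3 of the 7. With it, all 8 losses with windows of 5 kb were smaller. Calls were gained by autophagy and lysosome genes (higher-scoring 10720 peaks, promoter class), neuron markers (promoter class, 100 bp) and immune markers (either end of the span). By nearest gene, histones and splicing factors were gained within 10 kb, for 6 lists called, and keratin-associated genes without matching, where 3 were called. Motif and GC-based alternatives were not run. No paired analysis was possible because there was 1 ChIP library. Depth is unknown, so a missing peak does not show absence.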

Other observations

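The tRNA and ZNF exon patterns were found in the data, and the tests of the tRNA genes against other short RNA genes and by score and of ribosomal protein genes against other housekeeping lists were chosen after the results were seen. tRNA genes, transcribed by RNA polymerase III, were overlapped by a peak in 240 of 443 cases (54.2%, exact 95% interval 49.4 to 58.9%). The 195 peaks involved had a median score of 147 against 61 for all peaks. Counts by chromosome were 30 of 33 genes on chromosome 17, 85 of 155 on chromosome 6, 29 of 98 on chromosome 1 and 1 of 22 on chromosome 7. The highest score, 1499, lay over TRR-CCT3-1 on chromosome 16 (3151562 to 3153259), followed by 1396 over TRS-CGA1-1 and TRT-AGT5-1 on chromosome 17 (8138727 to 8139811), all named after their values were seen. Other genes of this polymerase also had peaks: RN7SL2 and RN7SL1, the signal recognition particle RNAs, with scores of 665 and 248, RN7SK, which holds P-TEFb inactive, with 387, and the RNase MRP and RNase P RNA genes RMRP and RPPH1 with 251 and 150. Y RNA genes had a peak in 3 of 4, U6 and U6atac genes in 4 of 6 and vault RNA genes in 2 of 4. The tandem 5S rRNA genes had 0 of 17. How reads that align to several places were treated is not given, so this does not show absence there.

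ZNF genes held peaks of another kind, wide and in the final exon. Of 521 exon peaks 225 lay in ZNF genes, and 222 of these (98.7%) were in the last exon, against 104 of 296 (35.1%) in other genes. Their median width was 1122 bp against 488.5 bp and their median score 137 against 44. ZNF180 had the highest score, 1161, over its exon 4 on chromosome 19 (44475965 to 44478181), then ZNF286A with 1107 on chromosome 17 (15715811 to 15717987) and ZNF544 with 1099, named after their values were seen. A last-exon peak was present in 216 of 509 ZNF genes (42.4%) and in 99 of 19465 others (0.509%), a log2 odds ratio of 7.17 (6.78 to 7.55). All these counts use the deposited exon class only. The 139 peaks of the 3' UTR class and 245 of the transcription termination class were kept apart, though last exons can hold such peaks. The shares given for either group may therefore be too low.

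For ribosomal protein promoters, weak peaks near the calling threshold are argued against by the higher-scoring 10720 peaks, with a log2 odds ratio of 1.81 (1.04 to 2.58). Signal at constitutively active promoters in general remains a candidate explanation. Ribosomal protein genes had a log2 odds ratio of 0.483 (-0.249 to 1.22; p = 0.23, Fisher's exact test) against 6 pooled housekeeping lists, which themselves had 1.30 (0.96 to 1.64) against the remaining genes. Against 9 single lists it ran from -0.12 for splicing factors to 1.39 for oxidative phosphorylation genes, with a median of 0.23, and none passed adjustment over 10 comparisons (lowest adjusted p = 0.12, Fisher's exact test). No biological explanation was tested here or below, since 1 ChIP library was analysed with no other group to compare.

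For tRNA genes, the peak density of the surrounding region is argued against by windows shifted by 5 kb, of which 4.36% overlapped a peak. Short non-coding RNA genes of any kind are argued against by 1.32% of snoRNA, snRNA and miRNA genes. Weak peaks are argued against by 92.3% of the tRNA-overlapping peaks lying among the higher-scoring 10720. The hypothesis that mTOR or a partner is held at polymerase III genes in these cells may be followed up, but a control antibody or mTOR-depleted library was not analysed here, so loci that many antibodies enrich stay open.

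For last exons of ZNF genes, the peak density of chromosome 19 is argued against by a log2 odds ratio of 6.71 (6.22 to 7.20) on the other chromosomes. Gene length is argued against by the percentile of 100 among 10000 random lists matched on it, whose mean share was 2.12%. Both values count the deposited exon class only, so last-exon peaks deposited as 3' UTR are missing. Long last exons and reads shared between related ZNF genes could not be weighed, since exon lengths and mappability were not used here. The pattern stays a hypothesis about these genes.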
